A study of Homo sapiens with 4 samples.

How the data were processed

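RNA from 4 samples of MDA-MB-468 cells, 2 wild type and 2 with mH2A1.2 knocked out, was measured on Illumina bead arrays. Per the labels, RNA was extracted with a QIAGEN RNeasy kit, checked on a Bioanalyser, and made into biotin-labelled cRNA with an Ambion MessageAmp kit. GenomeStudio is named in the submitters' processing notes, with no version given in the sources used here. The deposited table holds, per the file headers, the mean signal intensity of 47230 probes on each array and a detection p-value for each probe and array. Intensities are linear, were not normalized between arrays, and have lowest values between 99.5 and 104, so the background was not subtracted. A detection p-value is the chance that a probe's signal is no higher than that of negative controls on the same array. The authors' processed table holds log2 values of 47164 of these probes, with medians of 6.46, 6.45, 6.46 and 6.45 for wild type replicates 1 and 2 and knockout replicates 1 and 2. Its scale, centring and match to arrays were checked against the signals. Over 14052 probes, each column's deviations from the mean correlated at r = 0.974 to 0.987 with those of its own array and at most 0.53 with another. It is not centred by gene, and the normalization method behind it is not given in the sources used here. In that table, chosen after values were seen, ATP6AP1 on knockout replicate 2 has a log2 value of 1.57, where its signal gives 11.86.

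Arrays were assigned to samples by the description in the labels. Signals were corrected for background with limma's normexp method, with negative control statistics inferred from detection p-values and an offset of 16. They were then quantile normalized and put on the log2 scale (R 4.3.3, limma 3.58.1). Probes with a detection p under 0.05 on at least 2 arrays were kept, 19752 in all. Gene names came from GEO's platform annotation, which lists 30082 probes, 30074 with 1 gene symbol and 8 with several, and leaves 17148 unnamed here. Symbols were updated through the gene number for 30035 probes, with a gene table of assembly GRCh38.p14. No coordinates are given, since no build is named for the array. Of the kept probes 14977 had 1 symbol, and each of 11311 genes was represented by its brightest kept probe, with 2900 genes having more than 1. The brightest probe was also used where others of the gene disagreed, as the MACROH2A1 probes do.

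Knockout was compared with wild type by limma's linear model and moderated test, two-sided, with Benjamini-Hochberg adjustment over 11311 genes and a threshold of 0.05. Differences are knockout minus wild type on the log2 scale with the moderated standard error, and folds are on the normalized scale, which the offset shrinks for dim probes. A gene not detected on either array of a group has only a bound there. It is given as at least N-fold, against the higher of the lowest signal of a detected probe and the gene's own, on each array. The bound is computed from group means and does not allow for their error. Before the data were examined, 40 gene lists were fixed, of pathways, complexes and markers of other cell types, which overlap. The 38 with at least 5 measured members were tested by camera with a preset correlation between genes of 0.01, adjusted over the 38. Camera with the correlation estimated for each list, and fry, were run as alternatives. With an estimated correlation camera rests on the 2 residual degrees of freedom of these 4 arrays, which leaves it little power. The genes to name were also fixed. They are MACROH2A1, MACROH2A2, LOX, EZH2, the 10 largest differences past the threshold in each direction, or with fewer than 5 past it the 5 with the smallest p, and up to 4 members with the smallest p of each list described. Of lists that did not pass, those to describe were chosen after values were seen.

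The steps were tested on simulated data with 200 of 11311 genes changed in each of 10 runs for this comparison of 2 against 2 arrays. Genes were drawn independently and with the same variance in both groups. The real arrays differ from this, with 637 genes over 2-fold apart between the knockout arrays and 41 between the wild type arrays. The rates given here may therefore not hold for them. On average 65.8 genes were called, 63.3 of them truly changed. An unadjusted p under 0.05 was reached by 90.2% of genes changed by a log2 of 1, 98.1% of those changed by 2 and 4.94% of unchanged genes. Camera called 100% of lists shifted by 0.5 and 0.67% of unshifted lists, in data simulated without correlation between genes.

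Alternatives fixed beforehand were no background correction, scaling to equal medians, an offset of 50, no detection filter, detection p under 0.01 on all 4 arrays, the authors' values, the mean of probes per gene, an intensity trend with and without robust fitting, the replicate number as a block, every kept probe as a feature, a 2-fold minimum, and each array left out. All 4 arrays lay on 1 chip, so chip and group are not confounded, and no other batch is given in the sources used here. On the chip, replicate 1 of wild type and knockout lay at positions A and B, and replicate 2 at C and D.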

Results

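The series compared MDA-MB-468 cells, an established human breast cancer line, with cells of the same line labelled as depleted of mH2A1.2. This protein, macroH2A1.2, is a variant of histone H2A made by alternative splicing from the gene MACROH2A1 (older symbol H2AFY). The series title ties mH2A1.2 to the formation of bone-resorbing osteoclasts and to EZH2, the enzyme that methylates lysine 27 of histone H3. Total RNA was measured on 4 Illumina bead arrays of 1 chip, 2 for wild type and 2 for knockout. Detection p was under 0.05 for 18753 and 18991 of 47230 probes on the wild type arrays, and for 19817 and 19318 on knockout replicates 1 and 2. Median signals lay between 142.7 and 146.8 and mean signals between 454.9 and 497.9, the lowest of both on knockout replicate 2. With 2 arrays in each group, the number of arrays limits the precision. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

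The 2 wild type arrays were close to each other, and knockout replicate 2 lay farther from them than knockout replicate 1. Across 11311 genes, which are not independent replicates, the log2 signals of the wild type arrays correlated at r = 0.992, and 41 genes differed more than 2-fold between them. Knockout replicate 1 differed more than 2-fold from the wild type arrays in 377 and 416 genes, and knockout replicate 2 in 1547 and 1185. The knockout arrays differed from each other in 637 genes. The first principal component held 72.9% of the variance and placed the wild type arrays at -28.4 and -21.0, knockout replicate 1 at 5.7 and knockout replicate 2 at 43.7.

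MACROH2A1, the targeted gene, read lower on both knockout arrays at its brightest probe. Probe ILMN_2373495 gave log2 signals of 13.04 and 12.96 in wild type and 12.32 and 12.12 in knockout, a difference of -0.78 ± 0.14 (SE, n = 2 per group), or 1.72-fold lower. Probe ILMN_1746171 was 2.05-fold lower, with 10.66 and 10.54 against 9.68 and 9.46. Probe ILMN_1674034, annotated to the same transcript record as ILMN_1746171, went the other way, with 8.89 and 8.56 against 9.71 and 9.30, or 1.72-fold higher. The remaining probe, ILMN_2275437, was not detected on any array. Which splice forms each probe reaches, and whether it lies in the part that was removed, is not given in the sources used here, so these probes check the labels only in part. MACROH2A1 did not pass the test over all genes (limma adjusted p = 0.130), and the mean of its kept probes gave a log2 difference of -0.34. MACROH2A2, which encodes a related macroH2A protein, lay close to background at 6.09 and 5.93 in wild type and 6.14 and 5.97 in knockout.

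LOX, which encodes lysyl oxidase, a secreted enzyme that crosslinks collagen and elastin, read higher on both knockout arrays, and EZH2 read lower. LOX log2 signals were 8.68 and 7.74 in wild type and 10.10 and 10.38 in knockout, a difference of 2.03 ± 0.36 (SE, n = 2 per group), or 4.08-fold. LOX was fixed for reporting from knowledge of the study's published work. EZH2 differed by -0.70 ± 0.16 (SE, n = 2 per group), or 1.63-fold lower, with 9.16 and 9.07 against 8.57 and 8.25. Median scaling moved the median of all genes to 0.125. The EZH2 difference was then -0.46 ± 0.24 (limma adjusted p = 0.484), the smallest over the alternatives. Its dimmer probes differed by -1.04 and -0.72, the latter with overlapping groups. Neither gene passed over all genes tested (limma adjusted p = 0.130 for LOX and 0.158 for EZH2). Leaving out knockout replicate 1, LOX, EZH2 and MACROH2A1 passed, at limma adjusted p of 0.0182, 0.014 and 0.0132. Over all alternatives each reached up to 0.796, without wild type replicate 1.

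**Figure D1:**
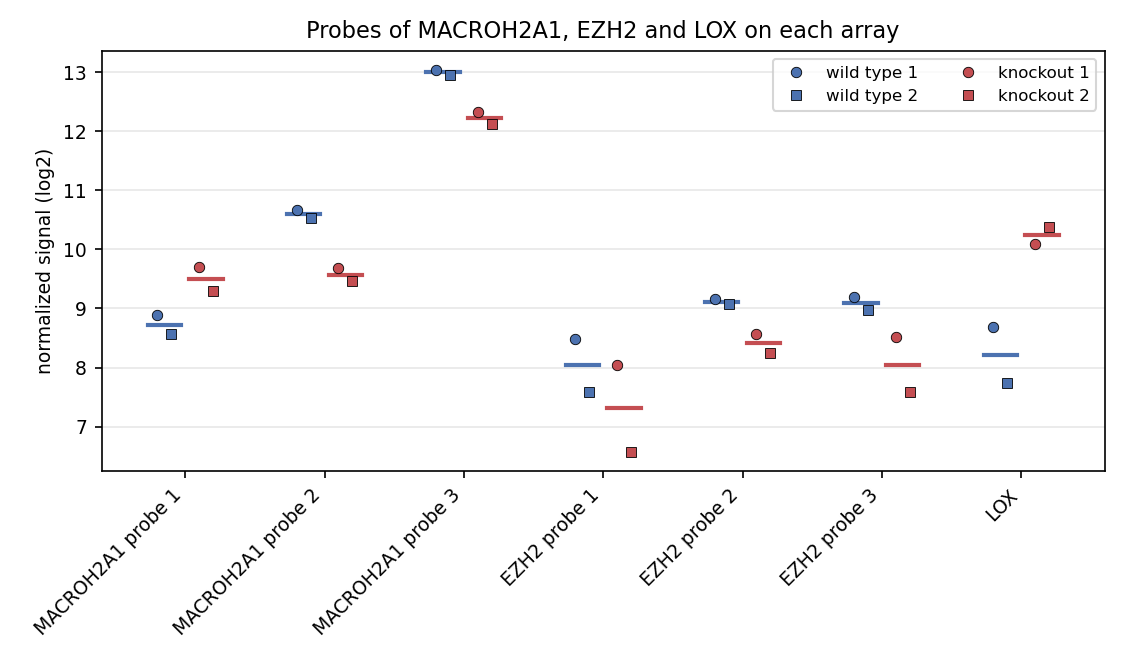
Normalized log2 signal of each detected probe of MACROH2A1, EZH2 and LOX on the 4 arrays, with circles for replicate 1, squares for replicate 2 and bars for the mean of 2 arrays per group. MACROH2A1 probes 1, 2 and 3 are ILMN_1674034, ILMN_1746171 and ILMN_2373495; the first lay higher on the knockout arrays and the others lower, while LOX lay at 10.10 and 10.38 in knockout against 8.68 and 7.74 in wild type.

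The 5 genes with the smallest p in each direction differed 2-fold or more at their brightest probe, though none passed over all genes. MT1F, a metallothionein, differed by 3.07 ± 0.19 on the log2 scale (SE, n = 2 per group; 8.40-fold). DPCD and CFAP300, which encode proteins needed for motile cilia, differed by 1.91 ± 0.11 and 1.77 ± 0.12, and PSMB9, a subunit of the immunoproteasome, by 1.66 ± 0.11. CEMIP, a protein of hyaluronan breakdown, was detected on 1 of 2 wild type arrays and on both knockout arrays, with a difference of 3.79 ± 0.26. In the other direction, the long noncoding RNA UCA1 differed by -2.26 ± 0.17, or 4.78-fold lower. SMIM13, a small membrane protein gene, differed by -1.97 ± 0.12. CRY1, a repressor of the circadian clock, MAPK8, the stress kinase JNK1, and SCML1, a gene related to Polycomb proteins, differed by -1.69 ± 0.14, -1.61 ± 0.13 and -1.50 ± 0.12. With the mean of their probes PSMB9 differed by 1.055 and MAPK8 by -0.86, the latter under 2-fold. With no background correction CFAP300, SMIM13 and MAPK8 differed by 1.15, -1.28 and -1.02. All 10 genes had a limma adjusted p of 0.122, the smallest of the comparison.

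Across the 11311 genes, 0 passed limma's moderated test at an adjusted p under 0.05, and 2283 had an unadjusted p under 0.05, against 566 by chance. Of these, 1090 were higher and 1193 lower in knockout, and 466 also differed at least 2-fold, 308 higher and 158 lower. In 54.1% of genes both knockout values lay above or both below the 2 wild type values, against 33.3% by chance. In the 2283, 47.7% were higher in knockout; scaling arrays to equal medians moved the median of all genes to 0.13 and that share to 86.0%. Leaving out knockout replicate 1 gave 3299 calls and leaving out knockout replicate 2 gave 312, in fits where the lone knockout array was assumed to vary like the wild type arrays. Leaving out wild type replicate 1 or 2 gave 0 calls, with 673 and 716 genes at an unadjusted p under 0.05.

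Genes of cell division lay lower in knockout as a group. Of 41 measured genes of mitosis and G2/M, 40 had negative differences, with a median of -0.49, and 30 had both knockout arrays below both wild type arrays. FOXM1, a transcription factor that drives mitotic genes, differed by -1.04 ± 0.18 (SE, n = 2 per group), AURKB, a mitotic kinase, by -0.65 ± 0.12, KIF14 by -0.71 ± 0.15 and NUSAP1 by -0.57 ± 0.12, or -0.37 under median scaling. Of 37 measured genes of DNA replication and S phase, 33 were negative, with a median of -0.39. RRM2, a subunit of ribonucleotide reductase, differed by -2.53 ± 0.69, with 10.16 and 9.34 in wild type against 8.12 and 6.33 in knockout. The replication licensing genes CDT1 and ORC1 differed by -1.03 ± 0.33 and -0.88 ± 0.27, and RFC5 by -1.06 ± 0.31. No member of either list passed over all genes, and none adjusted over the list alone. Both lists passed limma's camera test with its preset correlation (adjusted p = 6.87e-08 for mitosis and 4.49e-04 for S phase). Neither passed with an estimated correlation (camera adjusted p = 0.552 and 0.617). The mitosis median was -0.28 for knockout replicate 1 and -0.67 for knockout replicate 2 against wild type, and the S phase median -0.20 and -0.77. Under median scaling they were -0.29 and -0.20. With 1 array left out, RRM2 ran from -3.43 to -1.63, CDT1 from -1.47 to -0.60, ORC1 from -1.23 to -0.53 and RFC5 from -1.47 to -0.65. Without knockout replicate 2, S phase had a camera adjusted p of 0.176.

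Genes that present antigen lay higher in knockout, led by those of MHC class II. HLA-DRA, a chain of the HLA-DR receptor, had log2 signals of 9.30 and 8.66 in wild type and 11.60 and 12.22 in knockout, a difference of 2.93 ± 0.33 (SE, n = 2 per group), or 7.62-fold. HLA-DMA, which helps load peptides, differed by 2.03 ± 0.24, and HLA-DPA1, detected on 1 wild type array, by 3.52 ± 0.48. CD74, the invariant chain of class II, differed by 2.28 ± 0.35, and TAP2, a subunit of the peptide transporter, by -0.79 ± 0.19, or -0.36 with the mean of its probes; these were chosen after their values were seen. Of 16 measured members 0 passed over all genes, and adjusted over the list alone 7 were higher and 1, TAP2, was lower. CIITA, the activator of class II transcription, was chosen after its values were seen and was not well above background in wild type. It differed by 0.20 ± 0.12 (limma unadjusted p = 0.173). Its bound of at least 1.15-fold equals that estimate, so no clear increase is shown. With 1 array left out CIITA ran from 0.13 to 0.27, and on the authors' values it differed by 0.42. The list had a median of 0.84 and passed camera (limma adjusted p = 2.16e-05), but not with an estimated correlation (adjusted p = 0.552). Its median was 0.44 for knockout replicate 1 and 1.23 for knockout replicate 2. Probes for HLA-B, HLA-C, HLA-F and HLA-G, genes of near-identical sequence, are uncertain as to which gene they read.

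Interferon-stimulated genes did not pass as a list, with 23 of 39 positive and a median of 0.13 (limma camera adjusted p = 0.0661, and 0.573 with an estimated correlation). IFI27 differed by 1.54 ± 0.23 on the log2 scale (SE, n = 2 per group), LGALS3BP by 1.197 ± 0.26, IFI35 by 0.82 ± 0.18 and OAS2 by 0.64 ± 0.13. No member passed over all genes or adjusted over the list alone. Over the alternatives the camera adjusted p of this list ran from 0.00841, without wild type replicate 2, to 0.573. It was 0.0339 without knockout replicate 2, and with all 4 arrays 0.0348 on the authors' values, 0.0384 with no detection filter and 0.0445 with the replicate number as a block. The median ran from 0.08 to 0.28, the latter under median scaling. Among 6 measured leukocyte markers, with a median of 0.25, 0.03 for knockout replicate 1 and 0.50 for knockout replicate 2, 0 passed over all genes or over the list alone. The list did not pass (limma camera adjusted p = 0.285, and 0.621 with an estimated correlation). CD14, a monocyte receptor subunit, differed by 1.27 ± 0.33, LAPTM5 by 0.46 ± 0.35, CD68, a lysosomal protein, by 0.35 ± 0.46 and CORO1A by 0.14 ± 0.12. With 1 array left out CD14 ran from 0.82 to 1.73, LAPTM5 from 0.04 to 0.89 and CD68 from -0.15 to 0.86.

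**Figure D2:**
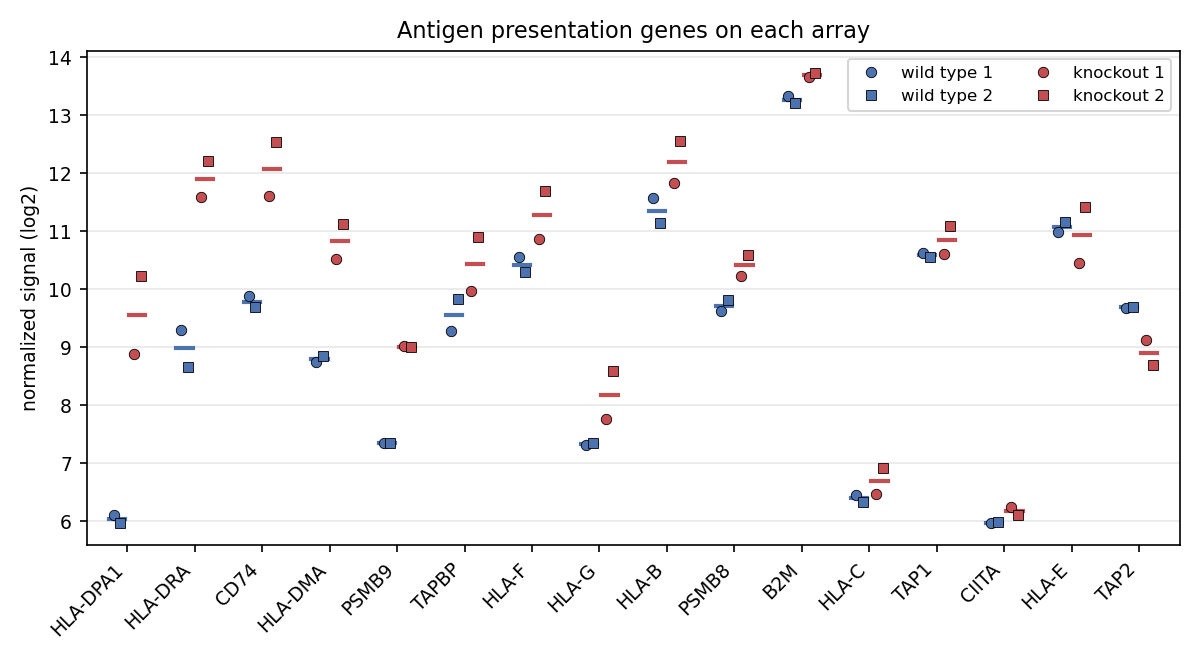
Normalized log2 signal of the 16 measured antigen presentation genes on the 4 arrays, ordered by difference, with circles for replicate 1, squares for replicate 2 and bars for the mean of 2 arrays per group. HLA-DRA lay at 11.60 and 12.22 in knockout against 9.30 and 8.66 in wild type, and TAP2 lay lower in knockout.

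Enzymes that modify collagen, and genes of the extracellular matrix, lay higher in knockout. Beside LOX, the collagen prolyl hydroxylases P4HA2 and P4HA1 differed by 1.21 ± 0.13 and 1.09 ± 0.25 on the log2 scale (SE, n = 2 per group), and the lysyl hydroxylase PLOD1 by 0.999 ± 0.21. Of 16 measured members 14 were positive, with a median of 0.48; 0 passed over all genes and 5 were higher adjusted over the list alone, these 4 and PLOD2, which was chosen after its values were seen. The list passed camera (limma adjusted p = 7.02e-04), but not with an estimated correlation (adjusted p = 0.552). In the matrix list 19 of 24 members were positive, with a median of 0.53. COL5A1 differed by 2.09 ± 0.40, COL18A1 by 1.71 ± 0.20, COL6A1 by 1.25 ± 0.35 and TNC, tenascin C, by 0.88 ± 0.24. Over all genes 0 passed, and adjusted over the list alone 1, COL18A1, was higher. The matrix list passed camera (limma adjusted p = 7.57e-04), but not with an estimated correlation (adjusted p = 0.552). Medians for knockout replicates 1 and 2 were 0.22 and 0.57 for the enzymes, and 0.42 and 0.54 for the matrix. Under median scaling the enzyme median was 0.72, and with no detection filter the matrix median was 0.07. COL6A1 ran from 0.77 to 1.73 with 1 array left out.

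Some markers of fibroblasts lay higher, in a list that shares genes with the matrix list. Of 16 markers 7 were measured, and 5 of these were positive, with a median of 1.02. That median is the value of ACTA2 (± 0.65), whereas DCN and COL6A3, both near background, differed by -4e-04 ± 0.12 and -0.02 ± 0.13. These members were chosen after their values were seen. Adjusted over the list alone 3 markers were higher, against 0 over all genes. The 3 were S100A4, a calcium-binding protein (1.45 ± 0.25 on the log2 scale, SE, n = 2 per group), COL5A1, and PDGFRB, a growth factor receptor (1.09 ± 0.29). COL1A1, a main collagen of fibroblasts, was not well above background in wild type, with 5.95 and 5.96 against 6.31 and 6.15. It differed by 0.27 ± 0.13 (limma unadjusted p = 0.0924), and its bound of at least 1.21-fold equals that estimate, so no clear increase is shown. The markers passed camera (limma adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.552). Their median was 0.35 for knockout replicate 1 and 1.38 for knockout replicate 2. With no detection filter it was 0.03 and their adjusted p 0.194, in a range over the alternatives from 0.00157 to 0.552. Markers of luminal breast lines also passed camera (limma adjusted p = 0.019; 0.552 with an estimated correlation), with 8 of 10 positive and a median of 0.15 that ran over the alternatives from 0.09, with no detection filter, to 1.44, with detection on all 4 arrays. The epithelial keratin gene KRT19 differed by 2.23 ± 0.36, CA12, a carbonic anhydrase, by 1.70 ± 0.41, MLPH by 1.44 ± 0.23 and XBP1 by 0.45 ± 0.12. These 4 were higher adjusted over the list alone and 0 over all genes. The luminal adjusted p was 0.053 under median scaling and 0.157 without knockout replicate 1, in a range from 0.00336 to 0.552.

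Genes of the response to low oxygen lay higher in knockout. PFKFB4, which sets the level of a glycolysis activator, differed by 1.98 ± 0.22 on the log2 scale (SE, n = 2 per group), DDIT4, an inhibitor of mTOR signalling, by 2.09 ± 0.39, and BNIP3L, a mitophagy receptor, by 1.02 ± 0.18. LOX belongs to this list too. Of 21 measured members 16 were positive, with a median of 0.71; 0 passed over all genes and 9 were higher adjusted over the list alone. The list passed camera (limma adjusted p = 4.49e-04), but not with an estimated correlation (adjusted p = 0.552), and its median was 0.56 for knockout replicate 1 and 1.04 for knockout replicate 2. Of 16 glycolytic genes 14 were positive, with a median of 0.39, at 0.25 and 0.37 for knockout replicates 1 and 2. The phosphofructokinases PFKL and PFKP differed by 1.10 ± 0.27 and 0.93 ± 0.21, and PGK1 and ALDOA by 0.45 ± 0.15 and 0.40 ± 0.13. None passed over all genes or adjusted over the list alone. The glycolysis list passed camera (limma adjusted p = 0.0132; 0.552 with an estimated correlation), with 0.0551 without knockout replicate 2 and a range over the alternatives from 0.00273 to 0.552, and its median was 0.603 under median scaling.

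Chaperones of the endoplasmic reticulum lay higher and heat shock genes lower. SYVN1 and EDEM1, of the degradation of misfolded proteins, differed by 1.22 ± 0.17 and 1.10 ± 0.19 on the log2 scale (SE, n = 2 per group), and the disulfide isomerase PDIA6 by 0.94 ± 0.14. By the mean of its probes SYVN1 differed by 0.72. Of 17 measured members of the chaperone list 14 were positive, with a median of 0.37. At an unadjusted limma p under 0.05, 5 were higher and 2 lower. None passed over all genes, and SYVN1, EDEM1 and PDIA6 were higher adjusted over the list alone. Of 15 heat shock genes 13 were negative, with a median of -0.31. HSPH1 differed by -0.82 ± 0.28 and STIP1 by -0.43 ± 0.15, and the near-identical genes HSPA1A and HSPA1B, which their probes may not tell apart, by -0.82 ± 0.14 and -0.48 ± 0.13. No heat shock gene passed over all genes or adjusted over the list alone. Both lists passed camera (limma adjusted p = 0.0105 for chaperones and 0.00992 for heat shock), and neither with an estimated correlation (adjusted p = 0.552). Medians for knockout replicates 1 and 2 were 0.25 and 0.61 for chaperones, and -0.19 and -0.43 for heat shock. Under median scaling, which moved the median of all genes to 0.125, the medians were 0.59 and -0.09. STIP1 and HSPA1B then differed by -0.225 and -0.28. HSPH1 ran from -1.17 to -0.46 with 1 array left out. Without knockout replicate 2 their adjusted p was 0.0596 and 0.0812, in ranges over the alternatives from 0.00336 and 9.79e-04 to 0.552.

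Factors secreted by senescent cells and genes of oxidative phosphorylation were the other lists higher in knockout by camera. Among the secreted factors, TIMP2, an inhibitor of matrix proteases, differed by 1.597 ± 0.34 on the log2 scale (SE, n = 2 per group), VEGFA by 1.36 ± 0.36, and the binding proteins IGFBP6 and IGFBP4 by 1.02 ± 0.25 and 0.94 ± 0.21. By the mean of its probes TIMP2 differed by 1.007. Of 24 measured members 17 were positive, with a median of 0.18 (limma camera adjusted p = 0.0261, and 0.552 with an estimated correlation). Among its interleukins and chemokines, chosen after their values were seen, IL1B and IL1A differed by 1.72 ± 0.63 and 1.21 ± 0.61. IL6, CXCL8, CXCL1 and CXCL2 differed by 0.19, 0.15, 0.04 and -0.02, and CCL20 by -0.47, each with overlapping groups. Of 44 genes of oxidative phosphorylation 34 were positive, with a median of 0.07 (limma camera adjusted p = 0.0445; 0.552 with an estimated correlation). SDHC, ATP5PD, NDUFB10 and COX8A differed by 0.55 ± 0.17, 0.44 ± 0.12, 0.38 ± 0.14 and 0.36 ± 0.13, and SDHC by 0.30 with the mean of its probes. No member of either list passed over all genes or adjusted over the list alone. Medians for knockout replicates 1 and 2 were 0.20 and 0.43 for the secreted factors, and 0.15 and 0.08 for oxidative phosphorylation. Under median scaling they were 0.38 and 0.28, and with no detection filter that of the secreted factors was 0.042. Without knockout replicate 2 the secreted factors had an adjusted p of 0.324, in a range from 0.00406 to 0.552. For oxidative phosphorylation it was 0.597 without knockout replicate 1 and 0.165 without wild type replicate 2, and 0.0844 on the authors' values, 0.0819 with detection on all 4 arrays and 0.064 with the replicate number as a block, in a range from 0.00308 to 0.597.

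**Figure D3:**
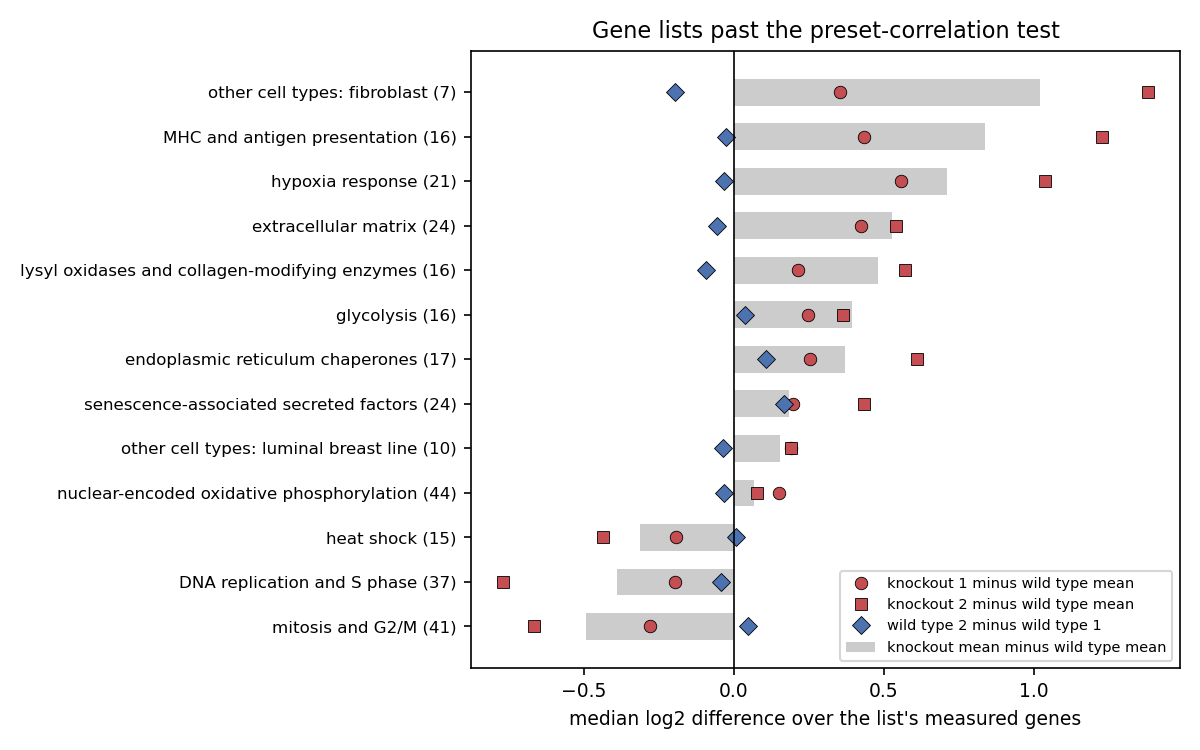
Median log2 difference over the measured genes, in parentheses, of the 13 lists that passed camera with its preset correlation. Grey bars show the knockout mean minus the wild type mean, red points each knockout array minus the wild type mean, and blue diamonds wild type replicate 2 minus replicate 1; the mitosis median was -0.28 for knockout replicate 1 and -0.67 for knockout replicate 2.

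Among genes of chromatin, the lists of histone variants, of PRC2 and of heterochromatin factors had negative medians and did not pass. The histone variant list shares CENPA with the mitosis list, and the heterochromatin list shares UHRF1 with the S phase list. Whether chromatin genes, EZH2 included, differed apart from the lower genes of cell division was not tested. PRC2 is the Polycomb complex that holds EZH2. Of 11 measured PRC2 subunits and H3K27 demethylases 9 were negative, with a median of -0.30. That median was -0.01 under median scaling, which moved the median of all genes to 0.125. AEBP2 and MTF2 differed by -0.41 ± 0.13 and -0.30 ± 0.13 on the log2 scale (SE, n = 2 per group), and by -0.13 and -0.01 under median scaling, and JARID2, another PRC2 partner, by 0.65 ± 0.19. Of 17 histone variants and chaperones 12 were negative, with a median of -0.24, at -0.07 for knockout replicate 1 and -0.20 for knockout replicate 2, in a range over the alternatives from -0.50 to -0.07, and -0.08 under median scaling. The centromeric histone gene CENPA differed by -1.04 ± 0.39, H3-3B by -0.93 ± 0.26 and CHAF1A, a subunit of a histone chaperone, by -0.70 ± 0.21. With 1 array left out CENPA ran from -1.57 to -0.52 and CHAF1A from -0.96 to -0.44. Of 17 heterochromatin factors 12 were negative, with a median of -0.22 and 0.03 under median scaling, at -0.14 and -0.37 for knockout replicates 1 and 2. CBX1, which encodes HP1 beta, differed by -1.57 ± 0.22, SUV39H1, a histone H3 lysine 9 methyltransferase, by -0.85 ± 0.18, TRIM28 by -0.82 ± 0.15 and DNMT1 by -0.55 ± 0.17, or -0.32 under median scaling. CBX1, SUV39H1 and TRIM28 were the 3 members lower adjusted over that list alone; no member of these 3 lists passed over all genes, and none adjusted over the lists of PRC2 or of histone variants alone. Each list had a limma camera adjusted p of 0.0661, and 0.552 with an estimated correlation. Without knockout replicate 1 histone variants and heterochromatin factors had an adjusted p of 0.0174 and 0.0119, the lowest of ranges reaching 0.552, and without wild type replicate 2 histone variants had 0.026. Both also passed under median scaling (limma adjusted p = 0.0309 and 0.0334) and on the authors' values (0.0348 and 0.044), and histone variants under the intensity trend (0.0404).

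Known targets of PRC2 did not pass as a list. Of 44 such genes 13 were measured, 7 positive and 6 negative, with a median of 0.02 (limma camera adjusted p = 0.857, and 0.926 with an estimated correlation) and a range over the alternatives from -0.009 to 0.146. The tumour suppressor gene RASSF1 differed by -1.11 ± 0.26 on the log2 scale (SE, n = 2 per group) and SLIT2, a secreted guidance factor, by -1.26 ± 0.29. RUNX2, a transcription factor of bone, differed by 0.90 ± 0.18, or 0.46 with the mean of its probes, and VASH1 by 0.36 ± 0.19, from 0.14 to 0.58 with 1 array left out. Genes of homologous recombination and the DNA damage response did not pass (limma camera adjusted p = 0.0661, and 0.552 with an estimated correlation), with 16 of 22 negative and a median of -0.24, at -0.10 for knockout replicate 1 and -0.31 for knockout replicate 2, and -0.045 under median scaling. EXO1, PARP1 and BLM differed by -0.94 ± 0.17, -0.84 ± 0.15 and -1.004 ± 0.20, and ATM, the kinase that signals DNA breaks, by 0.73 ± 0.15. Adjusted over the list alone 3 were lower and 1 was higher. No member of either list passed over all genes, and no PRC2 target adjusted over the list alone. Without knockout replicate 1 the repair list had a camera adjusted p of 0.0221, in a range from there to 0.552.

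Secreted factors that promote osteoclast formation, the question named by the title, did not pass as a list. LOX is not a member of that list, so its result does not cover LOX. Of 36 such genes 18 were measured, 12 positive, with a median of 0.09 (limma camera adjusted p = 0.251, and 0.552 with an estimated correlation). The cytokine gene IL1B differed by 1.72 ± 0.63 on the log2 scale (SE, n = 2 per group), with 8.86 and 10.25 in wild type against 10.71 and 11.85 in knockout. VEGFA differed by 1.36 ± 0.36, the growth factor gene TGFA by 0.93 ± 0.24 and CSF1, a factor osteoclast precursors need, by 0.48 ± 0.14, with CSF1 detected on 1 wild type array. The other 6 measured members that were negative include IL11 (-1.11 ± 0.63) and TGFB2 (-0.93 ± 0.63), both with overlapping groups and chosen after their values were seen. The list median was 0.03 for knockout replicate 1 and 0.26 for knockout replicate 2, and over the alternatives it ran from 0.03, with no detection filter, to 0.31, under median scaling. IL1B ran from 1.02 to 2.42 with 1 array left out. No member passed over all genes or adjusted over the list alone. TNFRSF11B, which encodes the decoy receptor osteoprotegerin and was chosen after its values were seen, differed by 0.36 ± 0.25, from 0.04 to 0.68 with 1 array left out. Osteoclast markers had 1 measured gene and endothelial markers 2, too few to test.

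Cytosolic ribosomal protein genes lay close to 0 as a list, with a median of -0.03 over 50 genes (limma camera adjusted p = 0.806, and 0.813 with an estimated correlation), and a median of 0.25 under median scaling. RPS7 differed by -1.03 ± 0.37 on the log2 scale (SE, n = 2 per group), RPL3 by 0.38 ± 0.12, RPS2 by -0.35 ± 0.12 and RPL22 by 0.34 ± 0.14, and none passed over all genes or over the list alone. RPS7 ran from -1.51 to -0.54 and RPL22 from 0.22 to 0.46 with 1 array left out, and under median scaling RPL3 and RPL22 differed by 0.63 and 0.52 and RPS2 by -0.08. A probe annotated to RNA28SN5, a 28S ribosomal RNA gene with near-identical copies, was chosen after its values were seen. That annotation was not checked against the probe's sequence and may not be right. It read 12.23 and 12.35 in wild type against 8.30 and 6.91 in knockout (limma adjusted p = 0.122). In all, 13 of 38 tested lists passed camera, 10 higher and 3 lower, and 0 passed with an estimated correlation. That version rests on 2 residual degrees of freedom, and with it 0 lists reached even an unadjusted camera p under 0.05. Luminal markers had an estimated correlation of -0.048, below the preset 0.01, yet their unadjusted camera p rose from 0.00551 to 0.101. Failing that version therefore says little against a list. The lists of TGF-beta targets and of mesenchymal genes of EMT, neither of which passed, had medians, means and tests that differed in sign.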

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

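All alternatives were fixed before the data were examined. The count of genes past the threshold stayed at 0 in each setting that kept all 4 arrays and ran from 0 to 3299 with 1 array left out. The count at an unadjusted p under 0.05 was 1493 under median scaling and 466 with a 2-fold minimum, against 2283, and 673 to 4662 with 1 array left out. Median scaling moved the median of all genes to 0.125; relative to it, the mitosis median of -0.29 and the antigen presentation median of 1.04 kept their directions. The number of lists past camera was 0 with an estimated correlation and 0 by fry, whose smallest adjusted p was 0.204 with 7 lists at an unadjusted p under 0.05, against 13, and 11 to 16 with 1 array left out. The robust trend was not run for lists, since camera has no such option, and fibroblast markers had too few members under detection on all 4 arrays. MACROH2A1 ran from -0.878 to -0.681 and LOX from 1.56 to 2.5 with 1 array left out, past the threshold without knockout replicate 1. Some values changed sign, and the cause was not tested. The camera direction of PRC2 targets turned under median scaling (median 0.146), no detection filter (-0.009) and detection on all 4 arrays (-0.007), and their median ran from -0.004 to 0.047 with 1 array left out. Ribosomal protein genes turned under median scaling (0.247) and the authors' values (0.042), and MACROH2A2 under the authors' values (-0.132). With 1 array left out MACROH2A2 ran from -0.045 to 0.127, CD68 from -0.152 to 0.862, GDF15 from -1.746 to 1.804 and IL24 from -2.355 to 0.933, among 28 of 131 genes moved by over 1.5 times; 21 moved so with no background correction, 19 under median scaling, 13 with the mean of probes and 5 each under the authors' values and an offset of 50. Over the other values of named genes, 1642 kept direction and side of the threshold and 143 passed it; of those of lists, 269 kept both, 39 lost the call and 14 gained it. With the replicate number as a block, 0 genes passed and 2910 had an unadjusted p under 0.05; oxidative phosphorylation lost its call (adjusted p = 0.064) and interferon-stimulated genes gained one (0.0445). Differences between replicates correlated at r = 0.443 across genes between the groups, but this rests on 2 pairs with no label of a shared batch. Samples of the same number also lay at neighbouring chip positions, A and B for replicate 1 and C and D for replicate 2. Detected probes made up 39.7% to 42.0% of each array, which limits what dim genes can show.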

Other observations

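The tests of leukocyte RNA, of HLA probes and of array labelling were chosen after their results were seen, and those of the other explanations before, on lists of ciliary, NRF2 and metallothionein genes drawn up after their first genes were noticed. Apart from DPCD, CFAP300, MT1F, CD14 and list members in the report, genes named here fall outside the rule for named genes and were chosen after their values were seen. Other genes with large differences lay higher on both knockout arrays without passing over all genes (limma adjusted p from 0.122 to 0.273 for those named here). They include HLA-DMB, a partner of HLA-DMA (2.33 ± 0.21 on the log2 scale, SE, n = 2 per group), MSLN, the surface protein mesothelin (2.56 ± 0.31), CLIC3 (2.67 ± 0.24) and SCG2 (2.95 ± 0.40). The complement genes C3 and CFB differed by 1.82 ± 0.26 and 3.08 ± 0.75, and LAMA5, a laminin chain, by 2.79 ± 0.93. TXNIP, which binds thioredoxin, differed by 3.01 ± 0.89 and LCN2, an iron-binding secreted protein, by 2.30 ± 0.93. With 1 array left out CFB ran from 2.02 to 4.13, LAMA5 from 1.62 to 3.95, TXNIP from 1.83 to 4.19 and LCN2 from 1.02 to 3.58. Lower on both knockout arrays were IL7R (-2.05 ± 0.20), ADAMTS6 (-2.44 ± 0.27) and CCND1, which encodes cyclin D1 (-1.37 ± 0.18).

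The knockout arrays lay on opposite sides of wild type for a pair of secreted factors. GDF15 read 7.76 and 8.63 in wild type, 6.45 on knockout replicate 1 and 10.001 on knockout replicate 2. IL24 read 10.01 and 10.13 in wild type, 7.72 on knockout replicate 1 and 11.004 on knockout replicate 2. Their group differences were 0.03 ± 1.27 and -0.71 ± 1.14 (SE, n = 2 per group).

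Antigen presentation genes lay higher on both knockout arrays. RNA from leukocytes stays open: the 6 measured leukocyte markers had a median of 0.247 (95% bootstrap bounds -0.052 and 0.869), on both sides of 0.571, which is 0.25 of the class II median. Over all 15 markers on the array the median was -0.02 (bounds -0.053 and 0.065), below 0.571, but it rests on markers near background, where differences are compressed: only 5 were detected on both knockout arrays, CD14 among them at 1.27 higher, and LYZ, TYROBP and PTPRC, at 5.84, 5.87 and 5.89, on neither. The 8 members outside the HLA family had a median of 0.555, with 7 positive. This goes against cross-hybridisation among HLA probes as the whole cause, though it stays open for single HLA probes. The bootstrap bounds of that median were 0.202 and 1.663, the lower only just above the cut-off of 0.2 set after the result was seen. Like the bounds for leukocyte markers, they resample genes and not arrays, so they do not measure the spread between samples. A response of the cells to the knockout may also account for the higher antigen presentation genes, as an untested hypothesis. So may a difference in origin between the knockout and wild type cultures.

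Knockout replicate 2 lay farther from wild type than knockout replicate 1. Weaker labelling of that array was not settled: its 19318 detected probes lay within the range of the other arrays, yet its mean signal of 454.9 was the lowest. A state of the cells that also differed between the replicate numbers in wild type could add to it, since wild type replicate 2 minus replicate 1 correlated with knockout minus wild type at r = 0.141 across genes, between the bounds of 0.1 and 0.2 set for either reading. The difference of replicate 2 from replicate 1 itself correlated at r = 0.443 across genes between the groups, which goes with a shared state but rests on 2 pairs. Samples of the same number also lay at neighbouring chip positions, so position is tied to the number. These explanations cannot be told apart from a stronger response of that sample to the knockout, since each group holds 2 arrays.

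DPCD, CFAP300, TCTN1 and BBOF1, all genes of cilia, were among the genes with the smallest p-values. TCTN1 differed by 1.85 ± 0.13 on the log2 scale and BBOF1 by 1.38 ± 0.13 (SE, n = 2 per group). Ciliary genes may lie higher as a group: the other 67 measured had 46 positive differences, a median of 0.145 and a camera p of 0.0023, but 0.0592 with an estimated correlation, with 13 higher and 5 lower at an unadjusted p under 0.05. Those with the smallest p were BBS2 (1.31 ± 0.18), IQCK (1.48 ± 0.22) and IFT43 (1.11 ± 0.18); DYNC2I1 differed by 1.74 ± 0.37, and in the other direction WDR35 by -0.75 ± 0.16 and IQCB1 by -0.75 ± 0.16. Of 10000 random lists matched on level, 0.04% reached that median, so it was rare among genes of similar level. These draws do not allow for correlation between genes. The list tested leaves out DPCD, CFAP300, TCTN1 and BBOF1. The draws therefore cannot tell whether noise of dim probes gave those genes their small p-values, and that explanation stays open.

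MT1F, NQO1, HMOX1 and ABCC3 differed by 3.07 ± 0.19, 1.597 ± 0.14, 2.63 ± 0.40 and 2.46 ± 0.48 on the log2 scale (SE, n = 2 per group), and the last 3 are known targets of the transcription factor NRF2, with NQO1 at 0.796 by the mean of its probes. The other 22 measured NRF2 targets showed no shift past the threshold, with a camera p of 0.731 and 12 positive, and at an unadjusted p under 0.05 AKR1C3 (2.06 ± 0.62), TKT (0.755 ± 0.23) and NQO2 (0.69 ± 0.17) were higher and SLC7A11 (-0.97 ± 0.31) lower. The other metallothioneins, listed with the zinc exporter SLC30A1 and 6 measured in all, may lie higher, with 6 positive and a camera p of 0.00395, but 0.173 with an estimated correlation, and MT1X and MT1E differed by 1.31 ± 0.24 and 0.78 ± 0.22. Without single arrays AKR1C3 ran from 1.21 to 2.90, TKT from 0.49 to 1.02, SLC7A11 from -1.36 to -0.59 and MT1E from 0.51 to 1.04. Metallothionein genes are near-identical in sequence, so their probes may read one another.

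The split into knockout and wild type gave 2283 genes at an unadjusted p under 0.05, and the highest of the other splits of the 4 arrays gave 389. Of 3 splits only 1, the real one, gave as many, and 3 splits are too few for a share under 0.05.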
